A study of Homo sapiens with 6 samples.

How the data were processed

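RNA was measured in BE(2)-M17 cells, an established human neuroblastoma line, in 6 libraries: 3 control libraries and 3 libraries from cells with knockdown of GOMAFU, the long non-coding RNA listed under the symbol MIAT. The groups and the replicate numbers (2, 3 and 4 in both groups) came from the sample labels. Nothing in the labels says whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Per the labels' protocols, cells received 100 pmol of small RNA with a lipid reagent, libraries were made from polyadenylated RNA with an RNA library kit, and paired reads of 150 bases were collected with a target of 100M reads per sample. The labels do not say whether strand was kept or counted. The labels do not say what the control cells received, nor which sequence was used for the knockdown.

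The deposited values were FPKM (fragments scaled by gene length and by the mapped total), with 1 column per library and 26372 genes. Per the submitters' processing notes, TopHat2 and Cuffdiff were used with the hg38 build; versions, annotation and filters are not given in the sources used here. FPKM divides by gene length and by the mapped total, so a few very abundant transcripts that rise in a library lower the values of all others in it. FPKM values are not counts, so no count model was run. The depth in reads is unknown from the table, but the smallest steps between low values of the same gene gave the depth of each library relative to control replicate 3: 1.10 and 0.972 for control replicates 2 and 4, and 1.07, 1.36 and 1.06 for knockdown replicates 2, 3 and 4. Depth therefore did not separate the groups.

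Genes with a mean of at least 1 FPKM over the 6 libraries were kept (12164 genes), and log2(FPKM + 1) values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, knockdown minus control, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all kept genes, and the threshold was an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. For MIAT an exact two-sided permutation test of the 3 against 3 FPKM values was added; its smallest possible p is 0.1. Groups were counted as not overlapping where all 3 values of one group lay above all 3 of the other, which chance gives for 10% of genes (5% each way).

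The design, 39 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Of 1317 list entries, 1255 matched the table by symbol and 57 by an older symbol, and 5 were not matched. The 36 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with adjustment over the lists, and beside it with camera with an estimated correlation and with fry. Members were also counted past the threshold over all genes and adjusted over the list alone. The genes named are 12 fixed genes (MIAT itself and genes of the pathway in the series title or of the disease field), the neighbours of MIAT as a group, and up to 2 members per list. Besides these, 12 genes higher and 12 lower are named. The rule asked for genes past the threshold with no overlap between groups, and none passed the threshold. They were therefore taken by the smallest p in each direction, with no condition on overlap. Small RNA genes, LOC symbols and clone-style names were skipped in the ranking. Genes singled out beyond that rule are marked as chosen after their values were seen. Coordinates are those of GENCODE release 29 (GRCh38, the same build as hg38), matched by symbol for 97.7% of the kept genes.

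The limma and camera steps were tested on simulated data with the spread of these libraries. Of 200 changed genes among 12164, the share recovered was 44% at a log2 change of 0.5, 82% at 1, 94% at 2 and 100% at 3. There were 8 false calls, and only the shifted list was called. The simulated noise was independent between genes and of the same spread in all 6 libraries. In the real data 1 library stands apart and members of a list move together. The simulation therefore shows that the steps run as meant, and gives neither the power nor the rate of false list calls here. The alternatives were other pseudocounts (0.1 and 0.01), no filter or a mean of at least 5 FPKM, upper-quartile scaling, quantile normalization, eBayes without the trend, robust eBayes, limma's library weights, the replicate number as a block, small RNA genes left out, a log2 change of at least 1 as well, and each library left out in turn. Leaving out both libraries numbered 4 was added after the data were seen, as was camera with an estimated correlation under each alternative.

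Values along the chromosomes were examined only after the gene-level results were seen. Genes with a mean of at least 5 FPKM were ordered by start position, and the difference of group means, limited to an absolute value of 0.5, was scanned for the single point at which the means on the 2 sides differed most relative to their error, with at least 20 genes on each side. The scan was tested on 200 simulated sets of 180 genes with a log2 step of -0.20, and found the break within 10 genes in 99.5% of them. That step was larger than the one later seen (medians of -0.06 before and -0.19 after), and the simulated noise was independent between genes. The 99.5% therefore does not give the accuracy of the real break. The break's interval was the 95% range of 1000 resamples of the residuals around the medians of both sides, and 10000 permutations of gene order were compared with the real order. Principal components, correlations and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.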

Results

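The series examined the miR-137 and GOMAFU non-coding RNA pathway in neuronal differentiation. Polyadenylated RNA from BE(2)-M17 cells, a human neuroblastoma line that can take on neuron-like features, was sequenced in 3 control libraries and 3 libraries of cells in which GOMAFU had been knocked down. The deposited FPKM values summed to 637153, 611348 and 615164 in control replicates 2, 3 and 4, and to 579365, 619208 and 597494 in knockdown replicates 2, 3 and 4. Between 11976 and 12314 genes reached 1 FPKM in a library. MYCN, the oncogene of this tumour type, stood at 2102 ± 91.3 FPKM in the controls and 1903 ± 179 in the knockdown libraries (SD, n = 3 each; adjusted p = 0.9998, limma). Control libraries correlated with one another at r = 0.988 to 0.996 across genes, whereas knockdown replicate 4 correlated with the other 5 libraries at 0.940 to 0.956. The first principal component held 72.0% of the variance and set that library apart from the rest.

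MIAT, the targeted transcript, was lower in all 3 knockdown libraries than in any control. This long intergenic non-coding RNA is retained in the nucleus and lies on chromosome 22, from 26646428 to 26676475 on the plus strand (GRCh38). It was measured at 5.38, 5.96 and 8.57 FPKM in the controls and at 1.27, 1.32 and 3.21 FPKM in knockdown replicates 2, 3 and 4, with means of 6.64 ± 1.70 and 1.94 ± 1.10 FPKM (SD, n = 3 each), so the knockdown mean was 29.2% of the control mean. The log2 difference was -1.42 (SE 0.27). It had the smallest p of all 12164 genes (unadjusted p = 0.00125), but adjustment over all genes left it short of the threshold (adjusted p = 0.9998, limma). The exact permutation test gave p = 0.1, the smallest value that 3 against 3 allows. MIAT passed the threshold when limma weighted the libraries by their spread (log2 -1.58, adjusted p = 0.00299) and, in a comparison added after the data were seen, without both libraries numbered 4 (log2 -1.54, adjusted p = 0.0118). The library weights were estimated from the same libraries. They were 7.98 for control replicate 3, 3.34 for knockdown replicate 2 and 0.153 to 0.915 for the others. The weighted fit therefore rests mainly on control replicate 3 and knockdown replicate 2. Over all 17 alternatives the adjusted p of MIAT ranged from 0.00299 to 1.

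**Figure D1:**
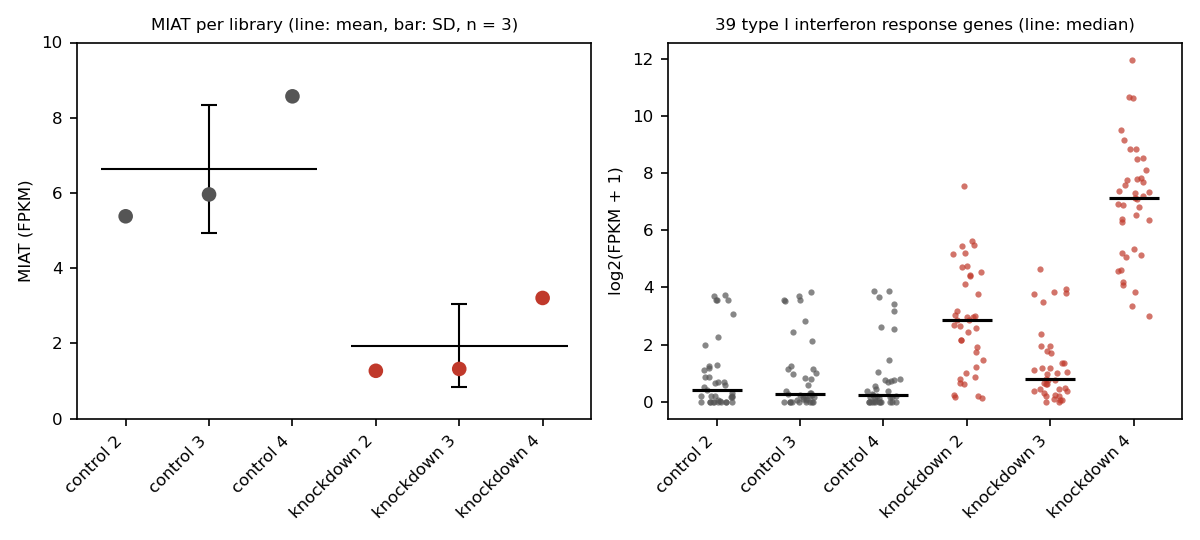
MIAT in FPKM per library (left; line, mean; bar, SD, n = 3) and the 39 measured type I interferon response genes per library as log2(FPKM + 1) (right; points, genes; line, median). MIAT lies between 5.38 and 8.57 FPKM in the controls and between 1.27 and 3.21 in the knockdown libraries, and the interferon genes are highest in knockdown replicate 4.

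The other transcripts gave larger p-values than MIAT. By limma 0 genes were past the threshold in either direction, with 118 higher and 145 lower at an unadjusted p under 0.05, where 608.2 of 12164 would be expected by chance. All 3 knockdown values lay above all 3 controls for 488 genes and below them for 529, together 8.36% of genes against the 10% that chance gives. With library weights, which favoured control replicate 3 and knockdown replicate 2, 9 genes were higher and 13 lower past the threshold.

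The 12 genes with the smallest p among those with a fitted difference above 0 included EGR1 and SPRY2, both members of the immediate early list fixed beforehand. None of the 12 passed the threshold. EGR1, a transcription factor, stood at 2.64 ± 0.61 FPKM in controls and 4.82 ± 0.99 in knockdown libraries. SPRY2, an inhibitor of receptor tyrosine kinase signalling, had a log2 difference of 0.31 (SE 0.08). ZFP36, which promotes decay of AU-rich mRNAs, stood at 5.02 ± 0.65 and 6.78 ± 0.20 FPKM, and RELB, a subunit of NF-kappa-B, at 1.61 ± 0.50 and 3.53 ± 1.12 FPKM (all SD, n = 3). The KRAB zinc finger genes ZNF304 and ZNF211 had log2 differences of 0.33 and 0.29 and lie, like TRAPPC2B (0.53), at the end of the long arm of chromosome 19. BRI3 differed by 0.39 and ALKBH6 by 0.34. GTF2IRD2B (0.46) and TRAPPC2B have near-identical copies, and IPO9-AS1 (0.64) and HOXD-AS2 (0.50) are antisense genes, so reads of their partners may be counted with them.

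The 12 genes with the smallest p among those with a fitted difference below 0 included, besides MIAT, LINC00526 with a log2 difference of -0.71 (SE 0.14). CHGA, which encodes the secretory granule protein chromogranin A, stood at 1707 ± 66.2 FPKM in controls and 1344 ± 113 in knockdown libraries (SD, n = 3). SLC29A4, a monoamine transporter, differed by -0.38, HSD17B8 by -0.42 and FAM163B by -0.28 on the log2 scale. The other 6 of the 12 lie on chromosome 22: MPST (-0.32), the mRNA export factor THOC5 (-0.26), the purine synthesis enzyme ADSL (-0.36), the mitochondrial assembly protein SAMM50 (-0.28), ATXN10 (-0.29) and the Golgi adaptor GGA1 (-0.28). None of these genes passed the threshold in limma. With library weights 11 of the genes named by the fixed rules did so besides MIAT, among them LINC00526 and CHGA.

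Genes of the type I interferon response rose as a list by camera (adjusted p = 1.78e-27; adjusted p = 0.61 with an estimated correlation). All 39 measured members had a fitted difference above 0, with a median log2 difference of 2.62. Of these, 30 had no overlap between the groups, where chance would give 1.95 in that direction. Some members near 0 FPKM in the other libraries reached the filter only through knockdown replicate 4, so this chance count does not apply to them. Members also moved together (estimated correlation 0.98), so the counts are not separate observations. ISG15, a ubiquitin-like modifier, was at 0, 0.15 and 0 FPKM in the controls and at 48.6, 2.40 and 1622 FPKM in knockdown replicates 2, 3 and 4. IFI6 averaged 10.3 ± 0.60 FPKM in the controls (SD, n = 3) and was 17.9, 2.34 and 391.6 times that mean in the knockdown libraries. IRF9, a transcription factor of the interferon response, was 5.71, 1.67 and 18.3 times its control mean, and OAS1, a sensor of double-stranded RNA, 20.6, 2.92 and 143 times. The genes ISG15 and IFI6 were singled out after their values were seen.

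No member of the interferon list passed the threshold over all genes, and 0 were past it adjusted over the list alone (smallest 0.135; 9 at an unadjusted p under 0.05). The sizes differed widely between libraries: the median of the list lay 1.97, 0.25 and 6.08 above the control mean in knockdown replicates 2, 3 and 4. Without knockdown replicate 4 the list's mean log2 difference went from 2.80 to 1.51 (camera adjusted p = 2.95e-22, or 0.788 with an estimated correlation). Over all alternatives the mean ran from 1.45 to 5.02 and the adjusted p by camera from 2.45e-42 to 2.65e-17.

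Immediate early genes, transcribed within minutes of a stimulus, also rose as a list by camera (adjusted p = 5.03e-08; adjusted p = 0.30 with an estimated correlation). Of 22 measured members 19 had a fitted difference above 0 and 7 were higher without overlap, against 1.1 by chance, with EGR1 and SPRY2 having the smallest p. The list's median lay 0.26, 0.16 and 0.12 above the control mean in knockdown replicates 2, 3 and 4. Over all alternatives the list's mean log2 difference ran from 0.15 to 0.44. No member was past the threshold over all genes or adjusted over the list alone (smallest 0.0677; 4 at an unadjusted p under 0.05). Without both libraries numbered 4, a choice made after the data were seen, the mean log2 difference went from 0.26 to 0.15 (adjusted p = 2.93e-07; adjusted p = 0.792 with an estimated correlation; 5.33e-09 to 0.000357 over all alternatives).

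Camera with the preset correlation of 0.01 placed 4 lists below other genes. Members of these lists moved together. Their estimated correlation was 0.65 for ribosomal protein, 0.49 for cholesterol biosynthesis, 0.75 for mitosis and 0.87 for oxidative phosphorylation genes. The counts of members given for these lists are therefore not separate observations, and the preset p-values make little allowance for this. Cytosolic ribosomal protein genes fell by a median of 0.13 on the log2 scale, with all 49 fitted below 0 and 7 lower without overlap against 2.45 by chance (adjusted p = 9.7e-16; adjusted p = 0.61 with an estimated correlation). The list's median was -0.21, -0.05 and -0.13 relative to the control mean in knockdown replicates 2, 3 and 4, against -0.08 in control replicate 3, and 49, 11 and 30 members lay below all controls in those knockdown libraries. RPL3 stood at 2263 ± 131 FPKM in controls and 1849 ± 124 in knockdown libraries, and RPS6 at 3417 ± 144 and 2913 ± 196 (SD, n = 3). This call was lost under quantile normalization (mean log2 -0.03, adjusted p = 0.538; 1.21e-22 to 0.538 over all alternatives), and RPL3 lies on the part of chromosome 22 described at the end.

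Cholesterol biosynthesis genes fell by a median of 0.16, with 23 of 24 fitted below 0 and 6 lower without overlap against 1.2 by chance (adjusted p = 1.02e-08; adjusted p = 0.61 with an estimated correlation). The sterol-regulated transcription factor SREBF2, on chromosome 22, differed by -0.24 and the sterol demethylase CYP51A1 by -0.21. The list's median was -0.08, -0.05 and -0.40 relative to the control mean in knockdown replicates 2, 3 and 4, against -0.07 in control replicate 4. Without knockdown replicate 4 the mean went from -0.17 to -0.06 (camera adjusted p = 0.0255, or 0.788 with an estimated correlation). Over all alternatives the adjusted p by camera ran from 2.83e-10 to 0.0255.

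Mitosis genes fell by a median of 0.16, with all 35 fitted below 0 and 4 lower without overlap against 1.75 by chance (adjusted p = 5.45e-10; adjusted p = 0.76 with an estimated correlation). The kinetochore motor CENPE stood at 23.8 ± 1.42 FPKM in controls and 17.4 ± 4.83 in knockdown libraries (SD, n = 3), and NDC80 differed by -0.14 on the log2 scale. The list's median was -0.04, -0.02 and -0.44 in knockdown replicates 2, 3 and 4, and the call ended without replicate 4 (mean log2 -0.04, adjusted p = 0.224), with library weights (adjusted p = 0.187) and without both libraries numbered 4 (adjusted p = 0.794), with a range of 3.5e-14 to 0.794 over all alternatives. Nuclear-encoded oxidative phosphorylation genes, with 47 of 50 fitted below 0, fell by a median of 0.10 (adjusted p = 2.95e-05; adjusted p = 0.97 with an estimated correlation). NDUFB7 differed by -0.18 and ATP5A1 by -0.21, and no member was lower without overlap, while 1 was higher. The list's median was -0.09, 0.07 and -0.27 in knockdown replicates 2, 3 and 4, against 0.11, 0.03 and -0.14 in control replicates 2, 3 and 4. Control replicate 4 thus lay below knockdown replicates 2 and 3, and the controls differed by more than the fall. In knockdown replicate 3, 0 of the 50 members lay below all controls and 11 above them. The call for oxidative phosphorylation ended without knockdown replicate 4 (adjusted p = 0.75) and without control replicate 2 (adjusted p = 0.242), with a range of 1.34e-11 to 0.75 over all alternatives. Its mean log2 difference, -0.09, was -0.0072 and -0.04 in those 2 settings, and -0.16 without control replicate 4 and -0.18 without knockdown replicate 3. No member of these 4 lists was past the threshold over all genes or adjusted over the list alone.

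**Figure D2:**
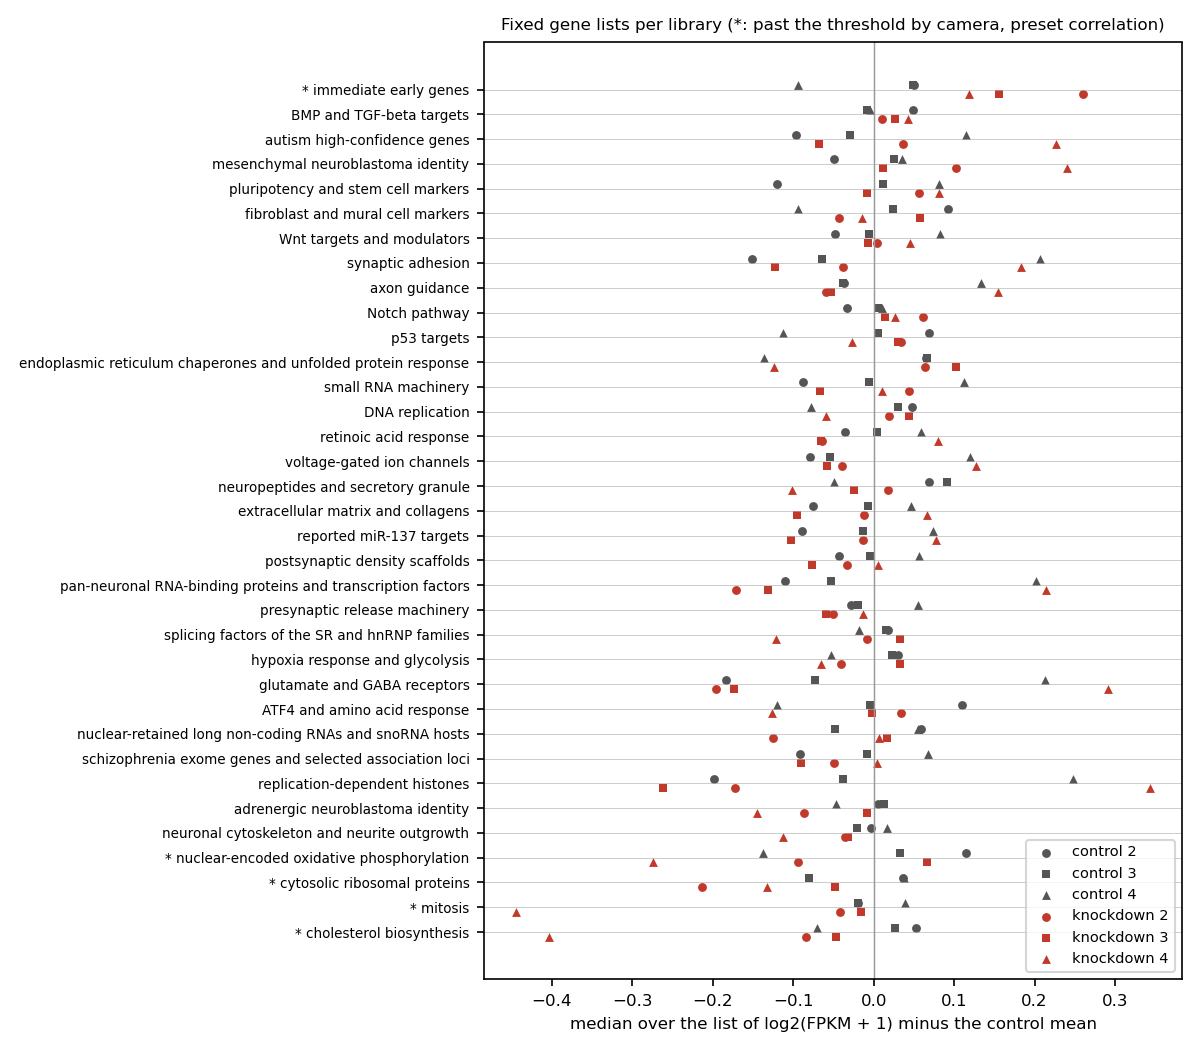
Median of each fixed list (vertical axis) in each library, as log2(FPKM + 1) minus the mean of the 3 controls (horizontal axis), for 35 of the 36 tested lists. The interferon list is left out because its median in knockdown replicate 4 was 6.08; mitosis and cholesterol biosynthesis lie lowest in that same library, at -0.44 and -0.40.

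No neuronal list passed the threshold with the settings chosen beforehand, though some did under alternatives. Neuronal cytoskeleton and neurite outgrowth genes had 25 of 33 members fitted below 0 with a median of -0.08 (adjusted p = 0.0624; past the threshold without control replicate 3, at 0.0324, without knockdown replicate 2, at 0.0297, and with no filter, at 0.0259; adjusted p = 0.724, 0.908 and 0.788 with an estimated correlation; 0.0259 to 0.672 over all alternatives, with a mean log2 difference of -0.05 that was -0.03 without knockdown replicate 4 and -0.01 with library weights), with STMN2, a microtubule regulator of growing axons, at 963 ± 70.7 and 833 ± 68.8 FPKM and MAP1A at 9.07 ± 1.12 and 11.1 ± 0.90 in control and knockdown libraries (SD, n = 3). The mesenchymal neuroblastoma identity list had a median of 0.06 (adjusted p = 0.0624; 0.0118 to 0.441 over all alternatives) and passed without control replicate 3 (0.0229), control replicate 4 (0.0118) or knockdown replicate 3 (0.0369; adjusted p = 0.724, 0.619 and 0.764 with an estimated correlation). With all 6 libraries it passed at a mean of at least 5 FPKM (0.0185), with no filter (0.0259) and under quantile normalization (0.0307; adjusted p = 0.727, 0.788 and 0.736 with an estimated correlation). Its mean log2 difference, 0.20, was 0.06 without knockdown replicate 4 (adjusted p = 0.441), 0.07 without both libraries numbered 4, 0.10 with library weights and 0.12 with no filter, and 0.33 with a pseudocount of 0.01; its median was 0.10, 0.01 and 0.24 in knockdown replicates 2, 3 and 4. The adrenergic identity list had a median of -0.06 (adjusted p = 0.259; 0.00195 to 0.883) and passed only without both libraries numbered 4 (adjusted p = 0.792 with an estimated correlation). Pan-neuronal RNA-binding proteins and transcription factors had a median of -0.03 (adjusted p = 0.625); without knockdown replicate 4 their mean was -0.15 and the list passed (adjusted p = 7.79e-05; adjusted p = 0.788 with an estimated correlation; 7.79e-05 to 0.872 over all alternatives), and without both libraries numbered 4 the mean was -0.06 (adjusted p = 0.0314; adjusted p = 0.792 with an estimated correlation); over all alternatives the mean ran from -0.15 to 0.09. Presynaptic release genes (adjusted p = 0.165), postsynaptic scaffolds (0.616), synaptic adhesion genes (0.616), glutamate and GABA receptors (0.625), voltage-gated ion channels (0.86), axon guidance genes (0.494) and neuropeptide and secretory granule genes (0.616) did not pass. Synaptic adhesion genes passed without control replicate 4 (adjusted p = 0.00879; adjusted p = 0.619 with an estimated correlation; 0.00879 to 0.981 over all alternatives, with means from -0.12 to 0.12).

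The lists closest to the pathway in the title did not pass either. Reported miR-137 targets had 11 of 25 members fitted above 0 and 14 below, with a median of -0.03 (adjusted p = 0.939). EZH2 and KDM1A, chromatin regulators reported as targets of this microRNA, had log2 differences of -0.04 and -0.07, and MIR137HG, the host transcript of miR-137, was at 0.94 ± 0.22 and 0.92 ± 0.19 FPKM (SD, n = 3). Splicing factors of the SR and hnRNP families had a median of -0.03 (adjusted p = 0.616). Among splicing proteins reported to bind GOMAFU, QKI differed by 0.13, SF1 by -0.03, SRSF1 by -0.12 and CELF3 by 0.02, each within 2 standard errors. The schizophrenia genes DISC1 and TCF4 differed by -0.08 and -0.06, and ERBB4 was at 0.06 FPKM in controls and 0.04 in knockdown libraries. The schizophrenia list (adjusted p = 0.258) had 1 member past the threshold adjusted over the list alone, MIAT itself (0.0288), and 0 over all genes. Without control replicate 2 the list passed (camera adjusted p = 0.0134, or 0.720 with an estimated correlation). Over all alternatives its adjusted p by camera ran from 0.0134 to 0.953. The list's mean log2 difference, -0.10, ran from -0.14 to -0.02. MIAT, the targeted transcript, is 1 of its 23 measured members and enters both this mean and the camera test. The list's median was -0.05, and the list was not tested without MIAT. Small RNA machinery (0.939), autism genes (0.165) and nuclear-retained non-coding RNAs and snoRNA hosts (0.491) did not pass; the autism list passed without control replicate 4 (adjusted p = 0.000731) and without knockdown replicate 3 (0.00280; adjusted p = 0.619 and 0.833 with an estimated correlation), with a range up to 0.998 and means from -0.02 to 0.10 over all alternatives.

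Signalling and stress lists gave adjusted p-values by camera of 0.625 for the Notch pathway, 0.86 for Wnt targets, 0.251 for BMP and TGF-beta targets, 0.967 for the retinoic acid response, 0.462 for p53 targets, 0.625 for ATF4 and amino acid response, 0.616 for endoplasmic reticulum chaperones, 0.616 for hypoxia and glycolysis, 0.877 for DNA replication and 0.96 for replication-dependent histones. Endoplasmic reticulum chaperones passed without knockdown replicate 4 (adjusted p = 0.0144; adjusted p = 0.788 with an estimated correlation; 0.0144 to 0.94 over all alternatives, with means from -0.05 to 0.07), and hypoxia and glycolysis without both libraries numbered 4 (0.029; adjusted p = 0.954 with an estimated correlation; 0.029 to 0.958, with means from -0.07 to 0.01). Of the 36 lists tested, 0 passed with an estimated correlation and 0 with fry (smallest adjusted p 0.297 and 0.373), against 6 with the preset. Estimating the correlation under the alternatives was added after the data were seen, and in those 18 settings 0 lists passed (smallest adjusted p 0.0944). In 7 lists, all short of the threshold, the mean or the median had the opposite sign to camera's direction. They were voltage-gated ion channels, DNA replication, small RNA machinery, miR-137 targets, histones, the retinoic acid response, and ATF4 and amino acid response. Other than schizophrenia genes, no list had a member past the threshold adjusted over the list alone.

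Markers of other cell types were few and did not pass. The fibroblast and mural list (8 measured, adjusted p = 0.86), the extracellular matrix list (20 measured, adjusted p = 0.86) and the pluripotency list (9 measured, adjusted p = 0.678) were tested. Only 3 Schwann and glial markers, 2 epithelial and liver markers and 1 blood and endothelial marker reached the filter, too few for a test. Among them CNP was at 15.7 ± 1.01 FPKM in controls and at 16.9, 15.2 and 46.9 FPKM in knockdown replicates 2, 3 and 4 (SD, n = 3), with the highest value in the library in which interferon genes were also highest.

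Genes near MIAT were measured as a group. All 8 measured neighbours had a fitted difference below 0, with a median of -0.12. HPS4 (-0.29) and TFIP11 (-0.16) were lower without overlap, which chance gives for 5% of genes in that direction and 10% in both together. None passed the threshold. After the values were seen, all genes with a mean of at least 5 FPKM were therefore laid out along the chromosomes. On chromosome 22 the median difference over 213 genes was -0.15, whereas the medians of the other chromosomes lay between -0.03 and -0.0014. The scan placed a step at 29259852, between XBP1 and RHBDD3, 2.61 Mb past the start of MIAT, with a 95% interval from 26521983 to 29788608. The 67 genes before it had a median of -0.06 and the 146 genes from there to the end of the chromosome one of -0.19, a level of 87.6% of the controls, and 91.8% of those 146 were below 0. Their median relative to the control mean was -0.21, -0.15 and -0.22 in knockdown replicates 2, 3 and 4, and 0.03, -0.0029 and -0.03 in the controls. In single knockdown libraries the step fell at 26443423, 25564849 and 29268009. The steps in knockdown replicates 2 and 3 lie before MIAT and outside the interval, which measures the spread between genes and not between libraries. Because the break was chosen on the same values, these medians describe the libraries and carry no test. The part past the break held 1.65% of the located genes tested and 56 of the 142 located genes that were lower at an unadjusted p under 0.05, but 0 of the 114 that were higher.

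**Figure D3:**
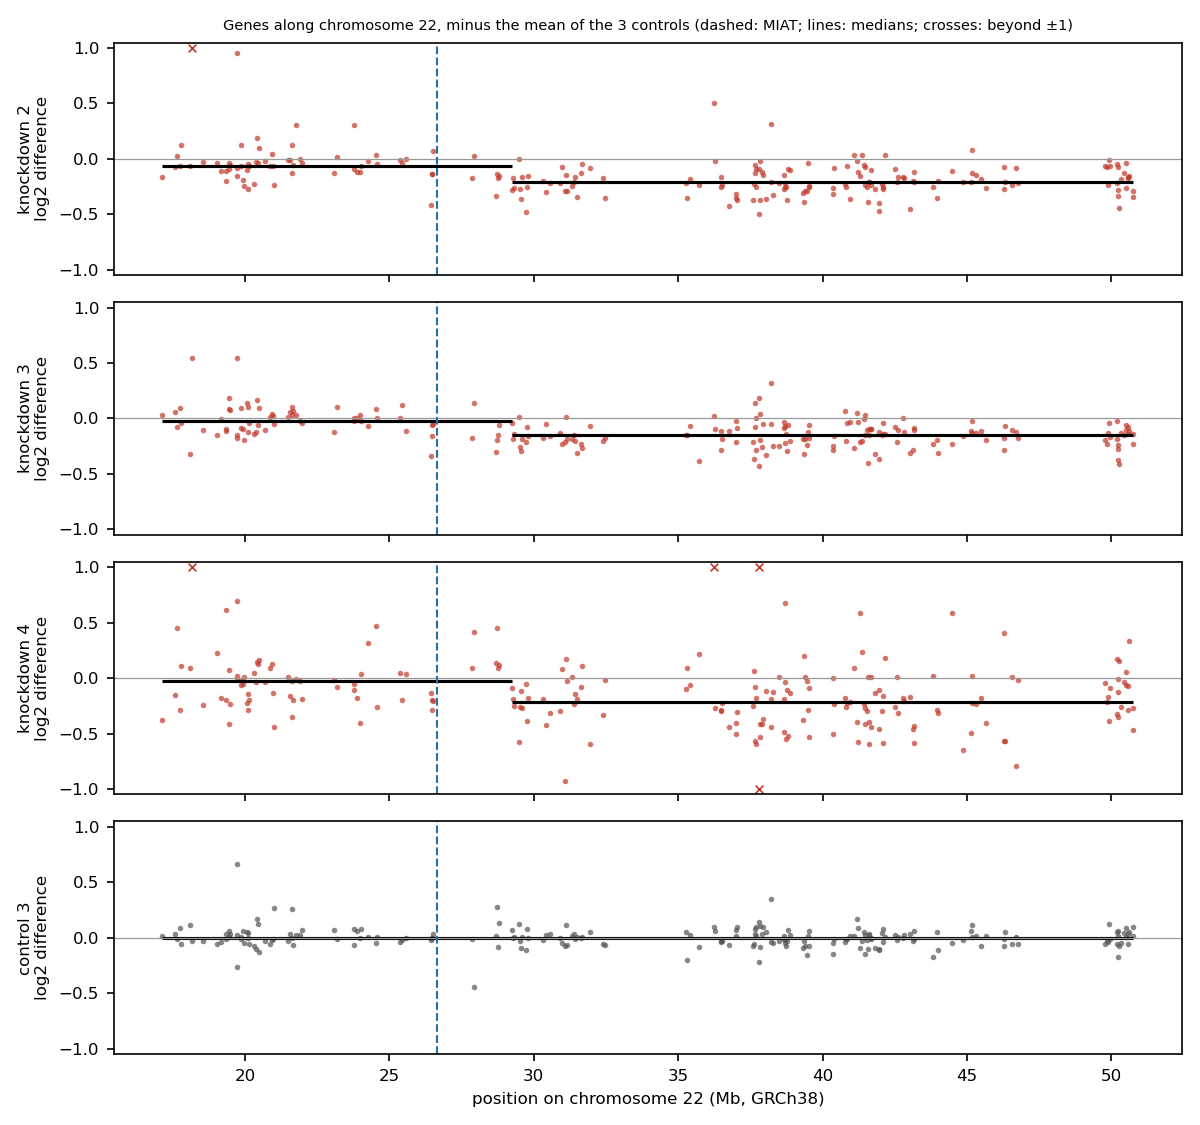
Each point is a gene on chromosome 22 with a mean of at least 5 FPKM, placed by its start in Mb (horizontal axis), with its log2(FPKM + 1) minus the mean of the 3 controls (vertical axis) in the 3 knockdown libraries and in control replicate 3, which is itself part of that mean. Black lines are medians before and after the step; past it they are -0.21, -0.15 and -0.22 in the knockdown libraries, the dashed line marks MIAT, and crosses are genes beyond the axis.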

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

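Leaving out both libraries numbered 4 was chosen after the data were seen, as were all alternatives for chromosome 22 and estimating the correlation under the alternatives; the others were planned. No called result reversed. With library weights 9 genes were higher and 13 lower instead of 0 and 0, and MIAT (-1.58) passed; the weights ran from 0.153 for knockdown replicate 4 to 7.98 for control replicate 3, and the cause was not tested. Without both libraries numbered 4, 0 genes were higher and 1 was lower, MIAT (-1.54). Leaving out 1 library at a time gave 0 genes either way, MIAT from -1.71 to -1.24 (adjusted p 0.267 to 0.9999) and 6 to 9 lists. The 6 lists became 0 with an estimated correlation, also under all 18 alternatives (smallest adjusted p 0.0944), 0 with fry, and 5 to 9 under the other settings. The 39 interferon genes, cholesterol and immediate early lists passed in all 18 settings of camera at the preset correlation, ribosomal genes in 17, oxidative phosphorylation in 16 and mitosis in 15. Over 646 pairs of list and setting, 6 calls were lost and 21 gained, 7 of these by the mesenchymal list and 4 by the neuronal cytoskeleton list. With the replicate number as a block, 0 genes passed either way (MIAT -1.42, adjusted p = 0.194) and 9 lists did, the 3 gained being BMP and TGF-beta targets (adjusted p = 0.0474), mesenchymal identity (0.0474) and neuronal cytoskeleton (0.0396), each at adjusted p = 0.879 with an estimated correlation. The values do not settle whether the numbers pair the samples. Deviations of same-numbered libraries correlated at 0.092, 0.168 and 0.322. Control replicate 2 correlated best with knockdown replicate 3 (0.318). Control replicate 4 correlated above 0 with knockdown replicate 4 alone (-0.19 and -0.34 with knockdown replicates 2 and 3). The deviations within a group sum to 0 for each gene. A correlation above 0 with 1 knockdown library therefore forces a correlation below 0 with another, so the negative values add no evidence of pairing. The splits given below also differ by whether the libraries numbered 4 lie together, and the main fit makes no allowance for this. MIAT had no value under a mean of at least 5 FPKM, which it does not reach. Of 109 single genes, 11 passed with library weights and 0 under other settings; 19 genes and 23 lists (by camera's direction), all short of the threshold with the settings chosen beforehand, changed sign somewhere, and some of these lists passed under an alternative. The median past the break on chromosome 22 stayed between -0.22 and -0.17. The 1-read steps fix only relative depth, so counting error of low genes such as MIAT is not known.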

Other observations

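The tests in this part, the counts of splits included, were chosen or run after the results they bear on were seen. The following 5 genes were chosen after their values were seen, and 0 passed the threshold in limma. The peptide transporter TAP1 was at 0.13, 0.03 and 0.02 FPKM in the controls and at 2.05, 0.05 and 119 FPKM in knockdown replicates 2, 3 and 4. HLA-B, a class I heavy chain, was at 0.21, 0.09 and 0.05 FPKM and then at 0.91, 0.45 and 55.7 FPKM, values that are uncertain because other class I genes share its sequence, while the light chain B2M was at 666 FPKM on average in the controls and at 802, 784 and 3433 FPKM. The chemokine CXCL10 was at 0, 0.06 and 0 FPKM and then at 2.44, 0.19 and 137 FPKM. IFNB1, the gene for interferon beta, was listed at 0 in all 3 controls and at 0.10, 0.08 and 23.01 FPKM in those libraries.

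The interferon genes differed widely between the knockdown libraries, and of these MIAT was highest, at 3.21 FPKM, in replicate 4, where the interferon genes were also highest. A response in knockdown replicate 4 alone is argued against by replicate 2, where 38 of 39 members exceeded all 3 controls. Chance gives this for 25% of members, but the members move together, so the count is not 39 separate tests. The argument rests on size: the list's median lay 1.97 above the control mean in replicate 2, against -0.02 to 0.0013 in the controls. Reads carried over from replicate 4 into replicate 2 would appear as one fixed share of each gene's excess, but the 90th percentile of that share was 9.37 times the 10th over the 39 members and 3.29 times over 15 members near 0 in the controls. For replicate 3 carry-over stays open as a source of part of its values: over those 15 members the share ran from 0.0468% to 0.372%, with a ratio of the same percentiles of 2.50, whereas it was 1.35% for OAS1 and 3.88% for IRF9, which goes against one fixed share, although both genes also varied between the controls. Whether lower MIAT or the delivered RNA and its transfection set off the response cannot be told apart. The treatment protocol given with every library, controls included, names 100 pmol of small RNA, but not what the control cells received. Outside that protocol, the titles, descriptions, sources and characteristics of 0 of the 3 control libraries name a delivered RNA.

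The lower values along distal chromosome 22 appeared in all 3 knockdown libraries, with a scan statistic of -6.92, -7.13 and -4.52 in replicates 2, 3 and 4 against -2.10 to 2.04 for a control set against the other controls. GC content or expression level as the whole cause is argued against: genes elsewhere matched on both had a median of -0.0089. On other chromosomes 0 of 5702 stretches of as many genes were as low. Those stretches overlap and are not matched on GC content or level, and the segment was picked for its low values. That count therefore describes the segment and is no test of a cause. An action of MIAT on its neighbours that fades with distance is argued against by the part of the segment farthest from it, whose median was -0.18 (95% interval -0.22 to -0.14), close to the -0.20 of the nearest part. A candidate explanation is that the knockdown cells carried fewer copies of distal 22q than the control cells, in all or some of the cells: the highest median of 50 neighbouring genes past the break was -0.18, under the lowest such value elsewhere (-0.07). This remains a hypothesis found and tested on the same values, DNA was not analysed here, and the interval of the break includes MIAT itself, whose log2 difference of -1.42 was far larger than that of the segment.

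The 6 libraries allow only 10 splits of 3 against 3, too few for a share under 0.05. For genes past the threshold the real split gave 0 and the highest other split 0, in both directions, so 10 of 10 splits gave as many. For lists the real split gave 6 and the highest other 15, and 7 of 10 splits gave at least as many. For the step on chromosome 22, with the break chosen anew each time, the real split gave a statistic of 7.32 and the highest other 4.31, so 1 of 10 splits reached it. In 10000 permutations of gene order 0 did (p = 1e-04, the smallest they can give). These reorder genes within chromosome 22, chosen after its values were seen, and treat genes as independent. That p therefore describes gene order and is no test of knockdown against control libraries. The split of control replicates 2 and 3 with knockdown replicate 3 from the rest gave 2282 genes at an unadjusted p under 0.05, against 263 for the real split, which points to a structure of the samples other than their groups: the 4 splits with both libraries numbered 4 on the same side gave 378 to 2282, and the 6 that part them, the real one included, gave 56 to 263. On chromosome 19 the scan's statistic was 4.22, the largest outside chromosome 22, with a median of 0.09 past 56810077, where ZNF304, ZNF211 and TRAPPC2B lie.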
